A study of Mus musculus with 11 samples.

How the data were processed

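RNA of fluorescence-sorted motor neurons from C57/BL6 mouse embryos was measured on 11 Affymetrix arrays, 1 per sample. Per the labels, a rhodamine dextran was taken up from the phrenic or radial nerve in trunk explants that carried the Hb9::GFP reporter, and motor neurons were sorted after dissociation of the spinal cord. Total RNA was extracted with Trizol, and biotinylated cRNA was made from 6 ug of it. The labels do not say whether replicates came from separate embryos or litters, so p-values measure the spread between arrays.

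The deposited values are on a log2 scale, 1 per probe set and array. Per the labels the authors used RMA, which corrects background, normalizes by quantiles and summarises the probes of a set, and the software version is not stated. The distributions of the probe set values were close but not identical between arrays, with medians from 4.48 to 4.63. RMA normalizes probes before it summarises them, so this does not show that the normalization was incomplete. The deposited table holds 45101 probe sets. The 64 control probe sets were left out of the tests and used for 3′ to 5′ differences, and 45037 were tested. Of these 34945 had 1 gene symbol, 932 several and 9160 none, and together the first covered 18193 genes. No other filter was applied, and the number of arrays limits the precision.

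Groups follow the cell type in the labels, with 4 phrenic, 4 C3-C5 GFP-only and 3 LMC radial arrays. A linear model with a mean per type was fitted in limma 3.58.1 under R 4.3.3, with moderated tests (8 residual and 2.92 prior degrees of freedom). Each type was compared with the unweighted mean of the other types and with each of them, in 6 comparisons. Two-sided p-values were adjusted by the method of Benjamini and Hochberg over all probe sets within each comparison, and an adjusted p under 0.05 counts as passing. A probe set was set apart in a type when it passed in the same direction against each of the other types.

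The gene lists, comparisons, the first set of alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 10 largest changes in each direction among passing probe sets whose arrays do not overlap, 1 per gene. It adds 20 identity genes whatever their result, and up to 4 members of each list with the smallest p. Each gene is represented by its probe set with the highest mean. The 43 lists were tested with camera at a preset correlation of 0.01, with adjustment over 258 tests. Camera with an estimated correlation and fry were run as alternatives. Counts adjusted over the list alone use the p-values of that list's genes only.

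Alternatives fixed at that time were quantile normalization of the arrays, centring on the median, leaving out dim probe sets, a floor at 5 on the log2 scale, a variance prior with a trend and robust fitting, array weights, a block for replicate number, gene means, fits of 2 types only, and leaving out each array in turn. Alternatives chosen after seeing the data were fits by array set, leaving out phrenic replicates 1 and 4 together, covariates for 3′ to 5′ differences, and a covariate for the mesenchyme list. The array sets were defined by the largest gap between the 25th percentiles of the arrays. Measures of array quality were compared by exact permutation tests, and arrays far from their replicates were found with Dixon's test (critical value 0.829 for 4 arrays). The model was tested on data simulated from probe set means, with noise drawn independently for each probe set and 2-fold and 4-fold changes added. There 5 to 12 of 45037 probe sets were false calls. These data hold no structure shared between probe sets, so this is not the error rate of the real arrays.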

Results

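RNA from sorted mouse motor neurons was hybridized to 11 Affymetrix arrays. The neurons came from Hb9::GFP embryos, in which motor neurons carry a green fluorescent reporter. A fluorescent dextran placed on a nerve of the trunk explant marked the neurons whose axons ran in that nerve. Phrenic motor neurons, which innervate the diaphragm, made up 4 arrays. Another 4 arrays held cells of segments C3-C5 with the reporter alone, written C3-C5 GFP-only. Lateral motor column neurons labelled through the radial nerve, a limb nerve, made up 3 arrays and are written LMC radial. Their sample titles name no segment, so in comparisons with them segment level cannot be told apart from cell type. The question was which genes set phrenic motor neurons apart from other motor neurons. The array medians lay between 4.48 and 4.63 on the log2 scale, and the number of arrays limits the precision. In 4 arrays, phrenic and C3-C5 GFP-only replicates 2 and 3, the 25th percentile lay between 3.18 and 3.20. In the other 7 it lay between 3.26 and 3.38. All 3 LMC radial arrays were among these 7. Differences below are log2 differences ± SE, with 4 phrenic, 4 C3-C5 GFP-only and 3 LMC radial arrays, and adjusted p-values are from limma. A mean below 5 lies near the array medians, so the fold against such a mean is written as at least the fold obtained with values below 5 raised to 5. Log2 differences against such a mean, and the order of genes by them, are as measured.

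Against the mean of the other 2 types, the largest increase in phrenic neurons was in Hs6st2 (3.57 ± 0.18), a heparan sulfate sulfotransferase, 11.9-fold higher (adjusted p = 2.41e-06), with a mean of 10.16 ± 0.36 (SD, n = 4) in phrenic neurons against 7.87 ± 0.02 (n = 4) in C3-C5 GFP-only and 5.31 ± 0.43 (n = 3) in LMC radial. Next were Synpr (3.54 ± 0.31), a synaptic vesicle protein, Vwc2 (3.39 ± 0.34) and Vwc2l (3.31 ± 0.26), secreted antagonists of bone morphogenetic proteins, Klf5 (3.31 ± 0.26), a transcription factor, and Cdh9 (3.31 ± 0.27), a cadherin. The set closed with Cadps2 (3.30 ± 0.11), which primes dense-core vesicles, Hs3st4 (3.23 ± 0.18), another heparan sulfate sulfotransferase, Adam12 (2.98 ± 0.22), a metalloprotease, and Sgms2 (2.92 ± 0.20), a sphingomyelin synthase. Largest among the decreases was Hoxc8 (-4.47 ± 0.63), 22.2-fold lower (adjusted p = 0.00241), followed by Grp (-4.37 ± 0.44), gastrin-releasing peptide, C1ql3 (-4.06 ± 0.35), Cbln4 (-3.72 ± 0.46), Cdh7 (-3.70 ± 0.26), Lmo3 (-3.56 ± 0.28), Pter (-3.50 ± 0.36), Opcml (-3.38 ± 0.23), Cartpt (-3.35 ± 0.22) and Tnr (-3.33 ± 0.34). C1ql3 and Cbln4 are secreted synaptic proteins, Cdh7 is a cadherin, Opcml an immunoglobulin adhesion protein and Tnr a matrix protein. The rule for named genes required that for each of these 20 every phrenic array lay beyond every array of the other types. Over all tested probe sets 3.85% met this.

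Of the list of phrenic column genes, 12 of 15 measured members were higher and 1 lower, with 12 higher and 1 lower adjusted over the list alone. They included Pappa (2.32 ± 0.15), Cdh10 (2.65 ± 0.18) and Pou3f1 (1.66 ± 0.12), a POU-domain transcription factor. The camera call (adjusted p = 3.26e-13) was lost at adjusted p = 0.0997 with an estimated correlation. This list draws on knowledge of phrenic neurons to which the study itself may have contributed, so its direction is not independent evidence. In Hox paralog groups 4 and 5, 5 of 6 measured genes rose and 0 fell (5 and 0 adjusted over the list alone), among them Hoxa4 (0.83 ± 0.12), Hoxa5 (0.74 ± 0.11), Hoxb4 (1.42 ± 0.22), Hoxb5 (0.62 ± 0.12) and Hoxc5 (0.48 ± 0.10). The adjusted p was 5.56e-06, and adjusted p = 0.0866 with an estimated correlation. The array means of this list were 9.899 ± 0.141 (SD, n = 4) in phrenic, 9.705 ± 0.142 (n = 4) in C3-C5 GFP-only and 8.707 ± 0.007 (n = 3) in LMC radial samples. Phrenic and C3-C5 GFP-only samples thus lay nearer each other than either lay to LMC radial samples. Of the lateral motor column list 6 of 17 genes fell and 1 rose (8 and 1 adjusted over the list alone). Those that fell included Gfra1 (-1.67 ± 0.18), a receptor for glial-derived neurotrophic factor, Foxp1 (-1.05 ± 0.12), Lhx1 (-2.29 ± 0.34) and Aldh1a2 (-1.38 ± 0.13), a retinoic acid synthesis enzyme. This call (adjusted p = 0.000256) was lost at adjusted p = 0.283 with an estimated correlation.

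Adhesion genes changed in both directions. In the classical cadherins 2 of 17 rose and 4 fell (2 and 6 adjusted over the list alone), Cdh9 and Cdh10 against Cdh7 and Cdh13 (-1.94 ± 0.15). In the delta-protocadherins 4 of 10 rose and 2 fell (5 and 2 adjusted over the list alone), with Pcdh11x (1.67 ± 0.15) and Pcdh10 (1.501 ± 0.17) higher and Pcdh9 (-2.36 ± 0.26) and Pcdh19 (-1.34 ± 0.13) lower. Camera called neither list (adjusted p = 0.159 and 0.249). Neuropeptides fell in 5 of 24 genes and rose in 1 (6 and 1 adjusted over the list alone), including Cartpt, Grp, Nxph1 (-1.55 ± 0.16) and Scg2 (-1.05 ± 0.12). The call (adjusted p = 0.0059) was lost at adjusted p = 0.294 with an estimated correlation. Of the transmitter receptors 9 of 58 rose and 6 fell (10 and 13 adjusted over the list alone), with the AMPA receptor subunit Gria3 (2.29 ± 0.12) and the serotonin receptor Htr1a (2.47 ± 0.26) higher. Of the 20 identity genes fixed beforehand, higher ones beyond those above were Isl1 (1.51 ± 0.37), Mnx1 (0.40 ± 0.09) and Alcam (0.45 ± 0.08), and lower ones were Lhx3 (-1.82 ± 0.42), Lhx4 (-1.46 ± 0.29), Hoxc6 (-0.43 ± 0.10) and Hoxa7 (-0.77 ± 0.17). Isl2 (-0.46 ± 0.15), Epha4 (-0.41 ± 0.11), Hoxc4 (0.06 ± 0.09) and Chat (0.17 ± 0.18) did not pass the test. A difference from the mean of 2 types need not hold against each. LMC radial against C3-C5 GFP-only gave -2.36 for Isl1 and -0.93 for Mnx1, beside 2.69 and 0.87 for phrenic against LMC radial. Both genes were thus lowest in LMC radial neurons. For Lhx3 and Lhx4 the phrenic mean lay below C3-C5 GFP-only but above LMC radial.

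Markers of other cells and of cycling cells moved with this comparison. The mesenchyme and cartilage list had 2 of 18 genes higher and 0 lower (7 and 0 adjusted over the list alone), and the cell cycle list 1 of 19 higher and 0 lower (4 and 0 adjusted over the list alone). Camera called both as higher (adjusted p = 0.00097 and 0.000192), and both calls were lost at adjusted p = 0.525 and 0.525 with an estimated correlation. In all, 1081 of 45037 probe sets were higher and 652 lower, 522 and 263 of them by 2-fold or more, and camera called 10 of 43 lists. Quantile normalization changed the share that was higher from 62.4% to 51.4%. The total of 1733 became 1035 with values below 5 raised to 5, 511 within the 7 arrays with the higher 25th percentile and 1048 with the array mean of the mesenchyme list as a covariate. Of the 58 called genes named for this comparison, 50 passed whichever single array was left out, and Hoxa7, Hoxb5, Hoxc5, Hoxc6, Isl1, Lhx3, Lhx4 and Mnx1 did not (the highest adjusted p of each with 1 array left out lay between 0.0513 and 0.102). The 50 also passed under the other alternatives fixed beforehand, where Sgms2 had no value once dim probe sets were left out.

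**Figure D1:**
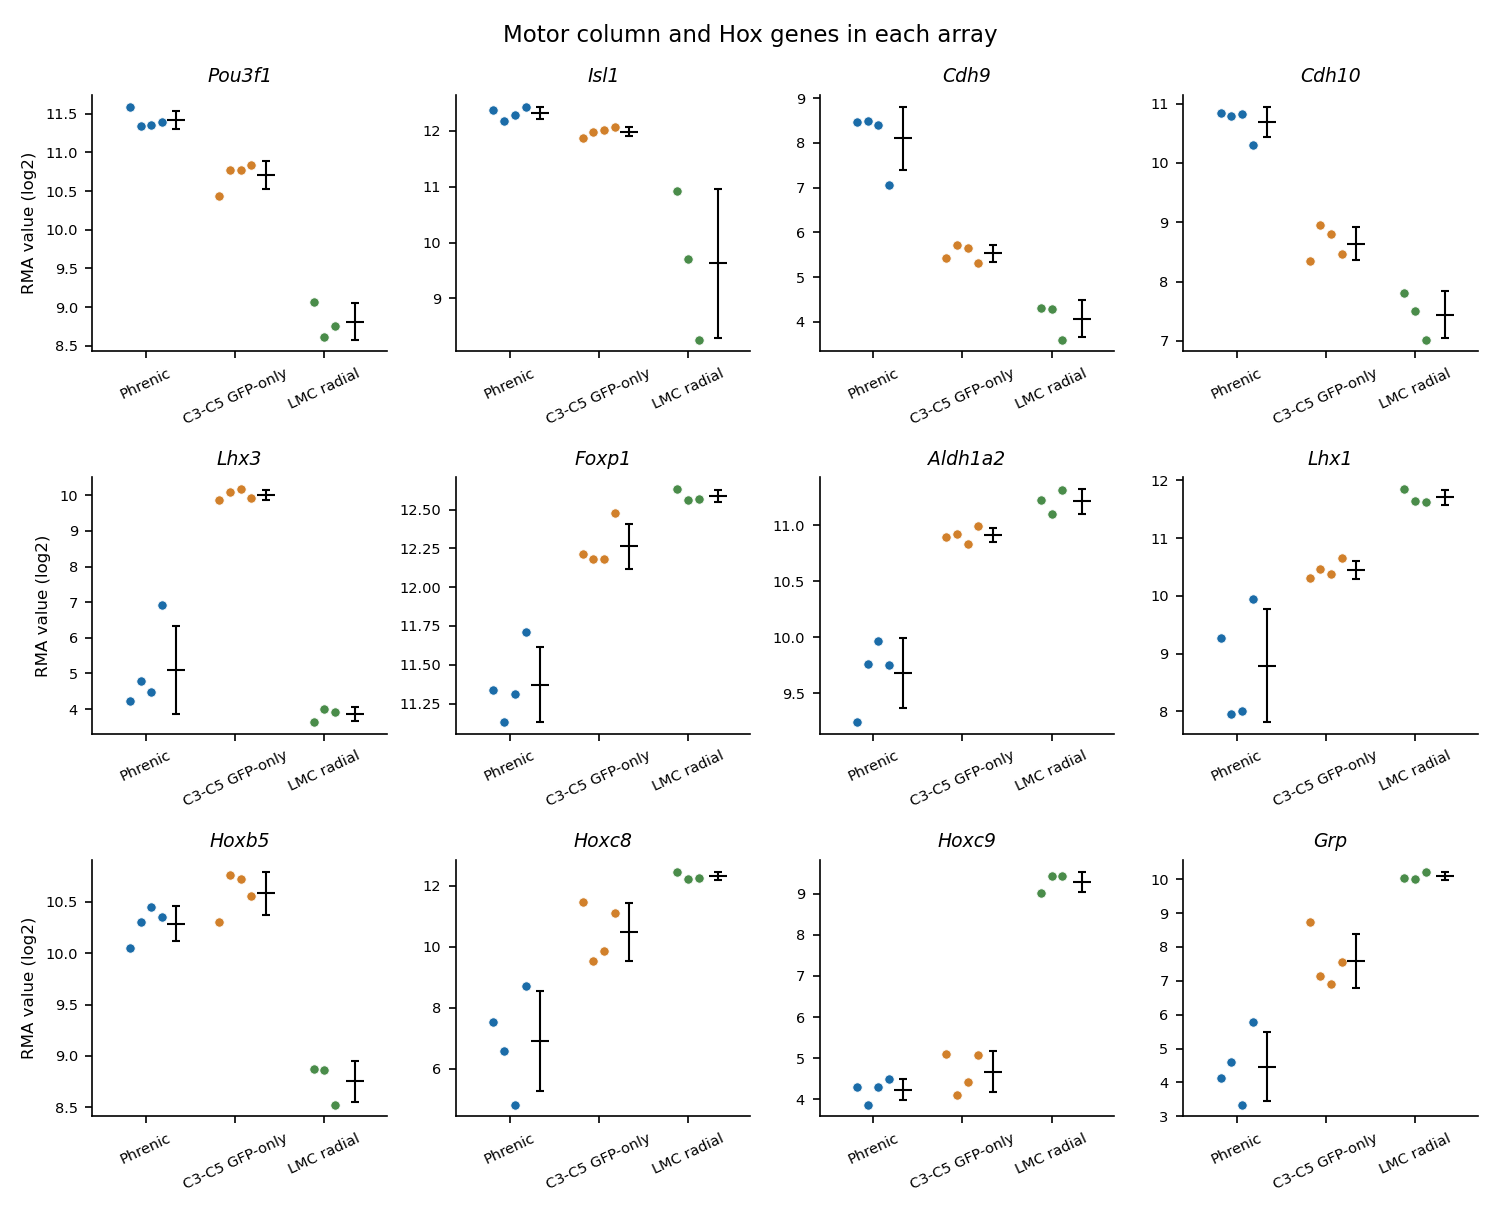
Motor column and Hox genes in each array. Each point is 1 array (y axis, RMA value on the log2 scale; x axis, cell type), and the bar is the mean ± SD of 4 phrenic, 4 C3-C5 GFP-only and 3 LMC radial arrays. Hoxc9 lies at 9.29 ± 0.24 in LMC radial and at 4.24 ± 0.26 in phrenic neurons, and Lhx3 lies at 10.01 ± 0.15 in C3-C5 GFP-only.

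In LMC radial neurons the largest increase over the mean of the other types was in Hoxc9 (4.83 ± 0.22), at least 19.3-fold higher (adjusted p = 1.86e-06), at 9.29 ± 0.24 (SD, n = 3) against 4.24 ± 0.26 (n = 4) in phrenic and 4.67 ± 0.49 (n = 4) in C3-C5 GFP-only neurons. It was followed by Grp (4.06 ± 0.47), Hoxc8 (3.60 ± 0.68), Brinp3 (3.40 ± 0.34), Cartpt (2.89 ± 0.24), Ntm (2.73 ± 0.19), Cbln4 (2.69 ± 0.49), Lmo3 (2.64 ± 0.30), Tnr (2.54 ± 0.36) and Hoxa9 (2.49 ± 0.45). The largest decrease was in Hs3st4 (-4.81 ± 0.20), at least 21.2-fold lower (adjusted p = 1.16e-06). Also lower were Epha5 (-3.78 ± 0.16), an ephrin receptor, Lhx3 (-3.71 ± 0.45), Hs6st2 (-3.71 ± 0.19), Irx5 (-3.65 ± 0.29), Sema3d (-3.43 ± 0.40), a secreted guidance cue, Synpr (-3.39 ± 0.33), Crnde (-3.34 ± 0.15), Met (-3.33 ± 0.25), the receptor for hepatocyte growth factor, and Dync1i1 (-3.27 ± 0.27). As the rule required, every LMC radial array lay beyond every other array for these 20 genes, as for 9.52% of all tested probe sets.

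In Hox paralog groups 4 and 5, 5 of 6 genes fell and 0 rose (5 and 0 adjusted over the list alone), with Hoxa4 (-1.54 ± 0.13), Hoxa5 (-0.997 ± 0.12), Hoxb4 (-1.66 ± 0.24), Hoxb5 (-1.68 ± 0.13) and Hoxc5 (-0.74 ± 0.11), while Hoxc4 did not pass (0.05 ± 0.09). The adjusted p was 5.34e-07, and adjusted p = 0.0688 with an estimated correlation. In paralog groups 9 to 13, 3 of 14 rose and 0 fell (7 and 0 adjusted over the list alone), Hoxc9, Hoxa9 and Hoxd10 (0.62 ± 0.14). For Hoxd10 all 11 arrays lay below 5, so its difference is one between values near background, and it did not pass with values below 5 raised to 5. The camera call of the list of groups 9 to 13 (adjusted p = 0.00394) was lost at adjusted p = 0.426 with an estimated correlation. The lateral motor column list rose in 8 of 17 genes and fell in 1 (9 and 2 adjusted over the list alone), with Lhx1 (2.08 ± 0.36), Gfra1 (1.35 ± 0.19), Aldh1a2 (0.92 ± 0.14), Foxp1 (0.77 ± 0.12) and Epha4 (0.57 ± 0.11) higher and Pou3f1 (-2.25 ± 0.13) lower. Its adjusted p was 0.00106, and adjusted p = 0.325 with an estimated correlation. Motor neuron identity genes fell in 6 of 20 and rose in 0 (11 and 1 adjusted over the list alone), including Mnx1 (-0.90 ± 0.10), Nkx6-1 (-1.69 ± 0.21), Lhx4 (-1.91 ± 0.31) and Isl1 (-2.52 ± 0.40). This call (adjusted p = 1.27e-06) held at adjusted p = 0.0414 with an estimated correlation.

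The medial and hypaxial column list fell in 6 of 11 genes and rose in 0 (8 and 0 adjusted over the list alone), among them Lmo4 (-2.07 ± 0.17) and Mecom (-2.39 ± 0.24). The adjusted p was 1.18e-08, and adjusted p = 0.0688 with an estimated correlation. This list shares members with the motor neuron identity list, among them Mnx1 and Lhx4. The AMPA receptor subunit Gria3 (-2.94 ± 0.13), the semaphorin receptor Plxnc1 (-2.36 ± 0.23), neuropeptide Y, Npy (-3.01 ± 0.28), and the cadherins Cdh9 (-2.75 ± 0.29) and Cdh10 (-2.22 ± 0.19) were lower as well. Cholesterol synthesis rose in 2 of 16 genes and fell in 0 (5 and 0 adjusted over the list alone), Msmo1 (0.76 ± 0.18) and Lss (0.55 ± 0.14). That call (adjusted p = 0.000519) was lost at adjusted p = 0.152 with an estimated correlation. Isl2 (-0.56 ± 0.16), Hoxc6 (0.29 ± 0.10), Alcam (-0.20 ± 0.08), Chat (-0.66 ± 0.19) and Hoxa7 (0.48 ± 0.19) did not pass the test.

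In this comparison 1646 probe sets were higher and 1517 lower, 335 and 716 of them by 2-fold or more, and camera called 10 of 43 lists. Of the higher ones 75% had a mean below the median of all probe sets, against 10.7% of the lower ones. Centring each array on its median changed the share that was higher from 52.0% to 66.9%. The 3′ minus 5′ difference of the Actb control probe sets, a sign of RNA quality, was 1.06 ± 0.06 (SD, n = 3) in LMC radial, 1.72 ± 0.48 (n = 4) in phrenic and 1.53 ± 0.42 (n = 4) in C3-C5 GFP-only arrays. The total of 3163 became 782 with values below 5 raised to 5, 6864 with array weights, 860 with the Actb difference as a covariate and 551 within the 7 arrays with the higher 25th percentile. It was 4746 without phrenic replicate 4, 2096 and 1960 without C3-C5 GFP-only replicates 2 and 3, and 1573, 1580 and 1621 without LMC radial replicates 1, 2 and 3. Of the 50 called genes named for this comparison, 44 passed whichever single array was left out, and Epha4, Hoxa9, Hoxc8, Hoxd10, Lss and Msmo1 did not (the highest adjusted p of each with 1 array left out lay between 0.0501 and 0.175). The 44 also passed under the other alternatives fixed beforehand.

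In C3-C5 GFP-only cells the LIM-homeodomain gene Lhx3 (5.53 ± 0.42), known from medial motor column neurons, had the largest increase over the mean of the other types, at least 27.3-fold (adjusted p = 0.000153), at 10.01 ± 0.15 (SD, n = 4) against 5.11 ± 1.24 (n = 4) in phrenic and 3.85 ± 0.20 (n = 3) in LMC radial neurons. Further increases were in Sp8 (4.51 ± 0.26), St18 (3.37 ± 0.21), Lhx4 (3.37 ± 0.29), Tac1 (3.25 ± 0.39), the tachykinin precursor, Neurod2 (2.96 ± 0.34), Nkx6-1 (2.75 ± 0.19), Dgkk (2.66 ± 0.36), Agmo (2.66 ± 0.28) and Nptx2 (2.57 ± 0.17), a neuronal pentraxin. The decreases were smaller and included the gap junction gene Gja1 (-1.86 ± 0.38), Foxc1 (-1.80 ± 0.34), Gask1b (-1.77 ± 0.35), the basement membrane genes Nid1 (-1.70 ± 0.34) and Lama4 (-1.58 ± 0.26), Zfp36l1 (-1.65 ± 0.33), Cntnap4 (-1.65 ± 0.25), Tox (-1.40 ± 0.20), Itga1 (-1.40 ± 0.25) and Sparcl1 (-1.28 ± 0.16). By the rule every C3-C5 GFP-only array lay beyond the other 7 arrays for these 20 genes, as for 2.12% of all tested probe sets. With values below 5 raised to 5, only Tox and Sparcl1 of the decreases named here passed, and Lama4 and Itga1 shrank to -0.36 and -0.66.

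The medial and hypaxial column list rose in 6 of 11 genes and fell in 0 (9 and 0 adjusted over the list alone), with Lmo4 (1.99 ± 0.16), Mecom (2.28 ± 0.22), Isl2 (1.02 ± 0.15) and Mnx1 (0.50 ± 0.09) beside Lhx3 and Lhx4. Its call (adjusted p = 4.21e-12) held at adjusted p = 0.0414 with an estimated correlation. Motor neuron identity genes rose in 7 of 20 and fell in 0 (10 and 3 adjusted over the list alone), and that call (adjusted p = 2.32e-05) also held at adjusted p = 0.0414 with an estimated correlation. Both lists hold Mnx1, Lhx4 and Isl2, so their calls are not separate results. Neuropeptide genes rose in 4 of 24 and fell in 0 (5 and 0 adjusted over the list alone), with Nxph4 (2.48 ± 0.25), Sst (1.88 ± 0.32), the somatostatin precursor, and Npy (1.52 ± 0.26) beside Tac1. The call (adjusted p = 0.000184) was lost at adjusted p = 0.152 with an estimated correlation. The NMDA receptor subunit Grin2c (2.00 ± 0.09) and the Hox genes Hoxb5 (1.07 ± 0.12) and Hoxa4 (0.70 ± 0.12) were also higher, as was Pou3f1 (0.59 ± 0.12), and the protocadherins Pcdh11x (-1.07 ± 0.15) and Pcdh10 (-1.06 ± 0.17) were lower. Pou3f1 was higher there than in LMC radial neurons but lower than in phrenic neurons (0.72 for phrenic against C3-C5 GFP-only). Of the other identity genes, Lhx1 (0.20 ± 0.34), Isl1 (1.01 ± 0.37), Foxp1 (0.28 ± 0.12), Aldh1a2 (0.46 ± 0.13), Alcam (-0.25 ± 0.08), Epha4 (-0.16 ± 0.11), Chat (0.49 ± 0.18), Hoxc4 (-0.11 ± 0.09), Hoxa5 (0.25 ± 0.11), Hoxc5 (0.26 ± 0.10), Hoxc6 (0.14 ± 0.10), Hoxa7 (0.29 ± 0.17) and Hoxc8 (0.87 ± 0.63) did not pass.

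Mesenchyme and cartilage markers were lower in 1 of 18 genes and higher in 0 (8 and 0 adjusted over the list alone), the 1 being Fn1 (-1.28 ± 0.23), fibronectin. The array means of this list were 4.61 ± 0.15 (SD, n = 4) in C3-C5 GFP-only, 5.80 ± 0.72 (n = 4) in phrenic and 5.43 ± 0.52 (n = 3) in LMC radial samples. Its call (adjusted p = 1.13e-06) was lost at adjusted p = 0.343 with an estimated correlation. Camera also called as lower the lists of cell cycle, endothelium, interneuron, progenitor and macrophage or microglia genes (adjusted p = 0.00035, 0.00143, 0.00349, 0.0178 and 0.0231). In each of these 5 lists 0 genes passed, and adjusted over the list alone 5 cell cycle genes and 0 of the others did. In the same order the calls were lost at adjusted p = 0.537, 0.343, 0.525, 0.721 and 0.717 with an estimated correlation. In all, 311 probe sets were higher and 127 lower, 184 and 55 of them by 2-fold or more, and camera called 15 of 43 lists. Quantile normalization changed the share that was higher from 71.0% to 60.6%. The total of 438 became 200 with values below 5 raised to 5, 1758 with array weights, 140 with the array mean of the mesenchyme list as a covariate and 24 within the 7 arrays with the higher 25th percentile. It was 135, 119 and 215 without C3-C5 GFP-only replicates 2, 3 and 4, and 215 and 244 without LMC radial replicates 1 and 2. Of the 34 called genes named for this comparison, 18 passed whichever single array was left out, and Cntnap4, Fn1, Foxc1, Gask1b, Gja1, Hoxa4, Isl2, Itga1, Lama4, Mnx1, Nid1, Npy, Pcdh10, Pou3f1, Sst and Zfp36l1 did not (the highest adjusted p of each with 1 array left out lay between 0.0505 and 0.184). The 18 also passed under the other alternatives fixed beforehand, except Pcdh11x and Tox with the mean of all probe sets of a gene.

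Phrenic neurons and C3-C5 GFP-only cells come from overlapping segments, so this comparison contrasts neurons with and without the label from the phrenic nerve. The largest increases in phrenic neurons were in Sgms2 (2.62 ± 0.23), at least 1.91-fold higher (adjusted p = 0.000194), Vwc2 (2.62 ± 0.38), Shisa9 (2.58 ± 0.24), an auxiliary protein of AMPA receptors, Cdh9 (2.58 ± 0.31) and Synpr (2.46 ± 0.35). The set went on with Htr1a (2.43 ± 0.29), Cntn4 (2.35 ± 0.43), a contactin, Ahnak (2.34 ± 0.46), Pappa (2.31 ± 0.17), a protease of insulin-like growth factor binding proteins, and Col26a1 (2.31 ± 0.31). The largest decreases were in Lhx3 (-4.90 ± 0.47, adjusted p = 0.000385), Sp8 (-4.12 ± 0.29), C1ql3 (-4.04 ± 0.39), Cdh7 (-3.69 ± 0.29), Pter (-3.67 ± 0.41), Hoxc8 (-3.56 ± 0.71), St18 (-3.39 ± 0.24), Lhx4 (-3.22 ± 0.32), Cbln4 (-3.16 ± 0.51) and Grp (-3.12 ± 0.49). Lhx3 was at least 23.1-fold lower with values below 5 raised to 5, since some phrenic values, though not their mean, lay below 5. The rule required every phrenic array to lie beyond every C3-C5 GFP-only array for these 20 genes, as it did for 7.49% of all tested probe sets.

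Phrenic column genes rose in 8 of 15 and fell in 0 (10 and 1 adjusted over the list alone, not independent evidence), among them Cdh10 (2.05 ± 0.20), Pcdh10 (1.71 ± 0.20), Pou3f1 (0.72 ± 0.13) and Alcam (0.47 ± 0.09). The adjusted p was 3.74e-10, and adjusted p = 0.152 with an estimated correlation. The medial and hypaxial column list fell in 5 of 11 and rose in 0 (5 and 0 adjusted over the list alone), with Lmo4 (-1.28 ± 0.18) and Isl2 (-0.99 ± 0.16), at adjusted p = 6.25e-06 and adjusted p = 0.115 with an estimated correlation. Neuropeptide genes fell in 7 of 24 and rose in 0 (8 and 0 adjusted over the list alone), with Cartpt (-2.54 ± 0.25), Nxph1 (-1.47 ± 0.18) and Nxph4 (-2.26 ± 0.29), at adjusted p = 9.07e-06 and adjusted p = 0.112 with an estimated correlation. Foxp1 (-0.89 ± 0.13), Aldh1a2 (-1.23 ± 0.14) and Nkx6-1 (-2.54 ± 0.22) were also lower.

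**Figure D2:**
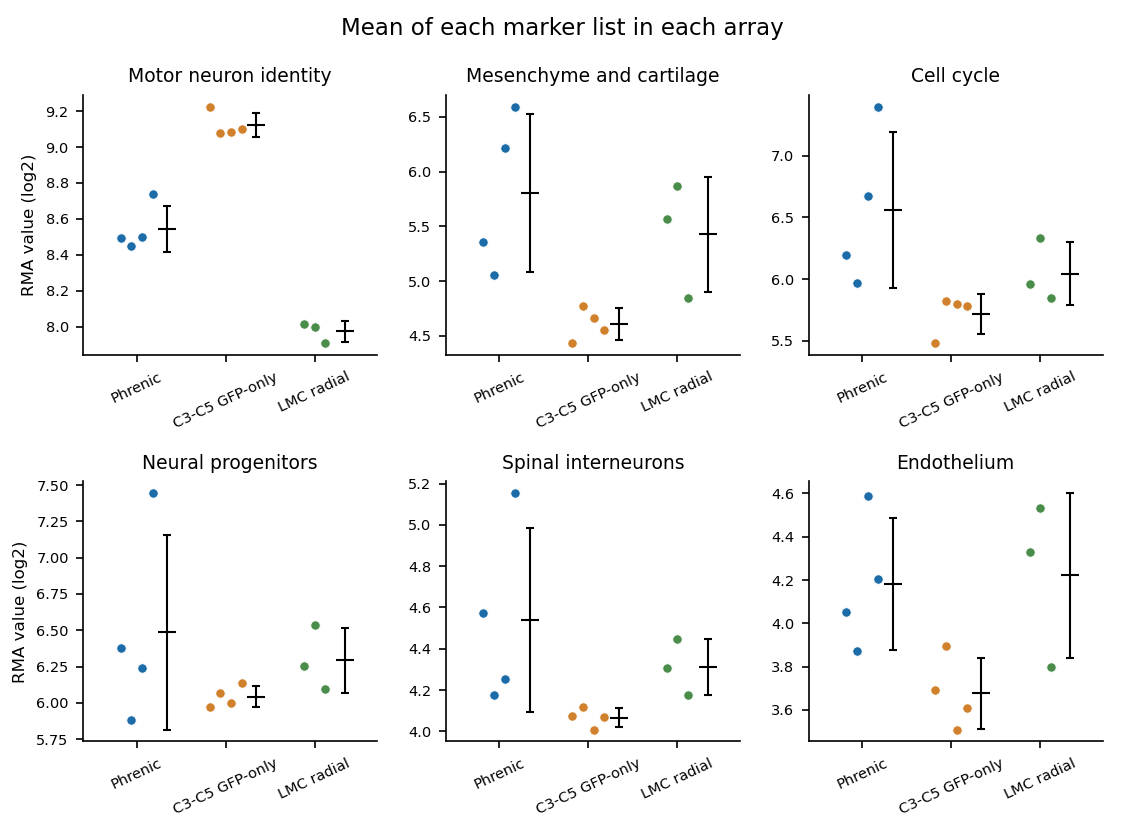
Mean of each marker list in each array. Each point is the mean RMA value (y axis, log2 scale) of a list's measured genes in 1 array, by cell type (x axis), and the bar is the mean ± SD of 4 phrenic, 4 C3-C5 GFP-only and 3 LMC radial arrays. The phrenic arrays of the mesenchyme and cartilage list lie between 5.05 and 6.59, and the C3-C5 GFP-only arrays between 4.43 and 4.78.

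Camera called 5 lists of markers of other cells and of cycling cells as higher in the phrenic samples, although few of their genes passed. Mesenchyme and cartilage markers passed in 2 of 18 genes, Fn1 (1.49 ± 0.26) and Postn (1.35 ± 0.28), and in 9 adjusted over the list alone. With values below 5 raised to 5 neither gene passed, and the Postn difference was 0.18, so most of it lay near background. The cell cycle list passed in 1 of 19, Cdk1 (1.77 ± 0.37), and in 9 adjusted over the list alone, and the progenitor list in 1 of 18, Slc1a3 (1.73 ± 0.38), and in 2 adjusted over the list alone. Interneuron and endothelium lists had 0 of 22 and 0 of 13 genes past the test, 0 and 0 adjusted over the list alone. The 5 calls were at adjusted p = 7.86e-07, 4.63e-06, 0.0231, 0.00356 and 0.00982. In the same order these calls were lost at adjusted p = 0.342, 0.468, 0.721, 0.525 and 0.468 with an estimated correlation.

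In this comparison 438 probe sets were higher and 444 lower, 257 and 279 of them by 2-fold or more, and camera called 12 of 43 lists. The total of 882 became 516 with values below 5 raised to 5, 325 with the array mean of the mesenchyme list as a covariate, 127 within the 7 arrays with the higher 25th percentile and 159 within the 4 with the lower one. It was 499, 458 and 540 without C3-C5 GFP-only replicates 2, 3 and 4. Of the 36 called genes named for this comparison, 27 passed whichever single array was left out, and Ahnak, Alcam, Cdk1, Cntn4, Fn1, Hoxc8, Postn, Pou3f1 and Slc1a3 did not (the highest adjusted p of each with 1 array left out lay between 0.0545 and 0.128). The 27 also passed under the other alternatives fixed beforehand, except Pter with values below 5 raised to 5, and Sgms2 had no value once dim probe sets were left out.

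Phrenic and LMC radial neurons were both labelled from their nerves, but segment level cannot be told apart from cell type here, Hox genes included. Increases in phrenic neurons over LMC radial were led by Hs3st4 (5.36 ± 0.22), at least 31-fold higher (adjusted p = 8.75e-07), Hs6st2 (4.86 ± 0.22), Synpr (4.62 ± 0.38), Epha5 (4.40 ± 0.18), Vwc2l (4.36 ± 0.31), Klf5 (4.33 ± 0.31), Cadps2 (4.31 ± 0.14), Vwc2 (4.16 ± 0.41), Adam12 (4.15 ± 0.26) and Dync1i1 (4.08 ± 0.30). Decreases were led by Grp (-5.62 ± 0.53), at least 29.7-fold lower (adjusted p = 0.000139), Hoxc8 (-5.38 ± 0.76), Hoxc9 (-5.05 ± 0.25), Cbln4 (-4.27 ± 0.56), Cartpt (-4.16 ± 0.27), Lmo3 (-4.13 ± 0.34), C1ql3 (-4.09 ± 0.43), Brinp3 (-3.93 ± 0.39), Tnr (-3.91 ± 0.41) and Ntm (-3.76 ± 0.22). By the rule no phrenic array overlapped an LMC radial array for these 20 genes, as for 18.7% of all tested probe sets. In Hox paralog groups 4 and 5, 5 of 6 genes rose and 0 fell (5 and 0 adjusted over the list alone), Hoxa4 (1.58 ± 0.14), Hoxa5 (1.16 ± 0.14), Hoxb4 (2.05 ± 0.27), Hoxb5 (1.53 ± 0.15) and Hoxc5 (0.82 ± 0.13), at adjusted p = 5.34e-07 and adjusted p = 0.0688 with an estimated correlation. Of the lateral motor column list 8 of 17 fell and 1 rose (8 and 1 adjusted over the list alone), with Lhx1 (-2.91 ± 0.41), Foxp1 (-1.22 ± 0.14), Aldh1a2 (-1.53 ± 0.16) and Gfra1 (-2.02 ± 0.22) lower and Pou3f1 (2.61 ± 0.14) higher. Its adjusted p was 0.00025, and adjusted p = 0.283 with an estimated correlation. The motor neuron identity list rose in 4 of 20 and fell in 0 (5 and 0 adjusted over the list alone), including Isl1 (2.69 ± 0.45) and Mnx1 (0.87 ± 0.11), at adjusted p = 0.00143 and adjusted p = 0.0866 with an estimated correlation. The ephrin receptor Ephb1 (3.21 ± 0.28) and the cadherins Cdh9 (4.04 ± 0.33) and Cdh10 (3.25 ± 0.22) were higher, and Epha4 (-0.66 ± 0.13) was lower.

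The cell cycle list had 0 of 19 genes past the test (0 adjusted over the list alone), and its call as higher in phrenic samples (adjusted p = 0.0353) was lost at adjusted p = 0.729 with an estimated correlation. Here 1567 probe sets were higher and 1412 lower, 932 and 444 of them by 2-fold or more, and camera called 12 of 43 lists. The share that was higher, 52.6%, was 42.5% with quantile normalization and 39.1% with each array centred on its median. The centring moved the median difference of all probe sets to -0.10. The total of 2979 became 1046 with values below 5 raised to 5, 1026 with the Actb difference as a covariate, 778 within the 7 arrays with the higher 25th percentile, and 1750, 1678 and 1799 without LMC radial replicates 1, 2 and 3. Of the 36 called genes named for this comparison, 35 passed whichever single array was left out, and Epha4 did not (highest adjusted p 0.0521 with 1 array left out). The 35 also passed under the other alternatives fixed beforehand.

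Higher in LMC radial than in C3-C5 GFP-only cells were Hoxc9 (4.62 ± 0.25), at least 19-fold (adjusted p = 1.59e-05), Brinp3 (2.86 ± 0.39), Grp (2.501 ± 0.53), Hoxa9 (2.48 ± 0.51), Smr2 (2.40 ± 0.23), Tspan8 (2.33 ± 0.31), Krt13 (2.32 ± 0.28), Gask1b (2.24 ± 0.42), Pik3r6 (2.14 ± 0.38) and Igf2 (2.02 ± 0.49). Lower were Lhx3 (-6.16 ± 0.51), at least 32.3-fold (adjusted p = 0.000173), Sp8 (-4.90 ± 0.31), Hs3st4 (-4.26 ± 0.22), Irx5 (-4.08 ± 0.33), Tac1 (-3.71 ± 0.48), Crnde (-3.63 ± 0.17), Lhx4 (-3.52 ± 0.35), Dgkk (-3.41 ± 0.44), St18 (-3.36 ± 0.25) and Abcc8 (-3.34 ± 0.32). As the rule required, the arrays of the 2 types did not overlap for any of these 20 genes, nor did they for 23.1% of all tested probe sets. With values below 5 raised to 5, Gask1b, Hoxa9, Igf2 and Pik3r6 did not pass, and the difference of Pik3r6 shrank to 0.71. The medial and hypaxial column list fell in 7 of 11 and rose in 0 (8 and 0 adjusted over the list alone), with Lmo4 (-2.71 ± 0.19) and Mecom (-3.12 ± 0.27), and its call (adjusted p = 1e-11) held at adjusted p = 0.0414 with an estimated correlation. Motor neuron identity genes fell in 9 of 20 and rose in 0 (10 and 1 adjusted over the list alone), with Nkx6-1 (-2.96 ± 0.23), Isl1 (-2.36 ± 0.45), Isl2 (-1.05 ± 0.18) and Mnx1 (-0.93 ± 0.11), and this call (adjusted p = 5.34e-07) held at adjusted p = 0.0414 with an estimated correlation. Mnx1, Lhx4 and Isl2 are in both lists, so the calls of the lists are not separate results. The Hox genes Hoxa4 (-1.49 ± 0.14), Hoxa5 (-0.83 ± 0.14), Hoxb5 (-1.83 ± 0.15) and Hoxc5 (-0.67 ± 0.13), with Pou3f1 (-1.89 ± 0.14), Npy (-3.02 ± 0.32) and Sst (-2.56 ± 0.39), were lower, and Pcdh19 (1.08 ± 0.16) was higher.

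The mesenchyme and endothelium lists had 0 of 18 and 0 of 13 genes past the test (2 and 0 adjusted over the list alone). Camera called both as higher in LMC radial samples (adjusted p = 0.00176 and 0.00954), and both calls were lost at adjusted p = 0.525 and 0.468 with an estimated correlation. Totals were 847 probe sets higher and 847 lower, 248 and 514 of them by 2-fold or more, and camera called 10 of 43 lists. Of the higher ones 79.5% had a mean below the median of all probe sets, against 11% of the lower ones. Centring each array on its median changed the share that was higher from 50% to 64.1%. The total of 1694 became 382 with values below 5 raised to 5, 6685 with array weights, 550 with the Actb difference as a covariate, 778 with the array mean of the mesenchyme list as a covariate and 98 within the 7 arrays with the higher 25th percentile. It was 2654 without phrenic replicate 4, 699 and 606 without C3-C5 GFP-only replicates 2 and 3, and 763, 807 and 993 without LMC radial replicates 1, 2 and 3. No phrenic array enters this difference, so leaving out phrenic replicate 4 changed only the estimate of the spread, shared by the 3 types. The SD of the difference between 2 replicates was 0.451 to 0.68 in phrenic and 0.245 to 0.396 in the other types. Of the 34 called genes named for this comparison, 27 passed whichever single array was left out, and Gask1b, Grp, Hoxa9, Hoxc5, Igf2, Isl1 and Pik3r6 did not (the highest adjusted p of each with 1 array left out lay between 0.0558 and 0.168). The 27 also passed under the other alternatives fixed beforehand, where Smr2 had no value once dim probe sets were left out.

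Genes that differed in the same direction from each of the other types were counted for each type. Phrenic neurons had 317 such probe sets higher and 213 lower, LMC radial 671 and 477, and C3-C5 GFP-only cells 110 and 8. In that order the counts became 43, 56, 30, 38, 13 and 2 within the 7 arrays with the higher 25th percentile. They were 133, 103, 213, 261, 69 and 6 with the array mean of the mesenchyme list as a covariate. They were 250, 194, 147, 184, 71 and 2 with the Actb difference as a covariate and 186, 141, 108, 163, 57 and 3 with values below 5 raised to 5. Independent lists of the same lengths would share 15.2 and 13.9, 26.6 and 29.5, and 8.35 and 8.24 probe sets in the same order, so the 8 as reported were no more than that. That count was higher with quantile normalization, centring, array weights, and a variance prior with a trend, as given below. Simulated unchanged groups that share the arrays, with noise drawn independently for each probe set, gave at most 1. This simulation holds no structure shared between probe sets. A split of the real arrays that follows the array set put 232 apart in C3-C5 GFP-only. With the shared type's arrays divided between the 2 comparisons, phrenic neurons had 115 to 258 higher and 122 to 179 lower probe sets over 6 divisions, and C3-C5 GFP-only cells 19 to 31 and 0 to 2. The 3 LMC radial arrays were not divided. Cdh9, Cdh10, Pappa and Pou3f1 were among those higher in phrenic neurons, Lhx3, Lhx4, Sp8 and Nkx6-1 in C3-C5 GFP-only cells, and Hoxc9 and Brinp3 in LMC radial neurons. Without phrenic replicate 4 the phrenic count higher was 529, and without C3-C5 GFP-only replicates 2, 3 and 4 it was 190, 180 and 195. The LMC radial count higher was 309, 268 and 445 without C3-C5 GFP-only replicates 2, 3 and 4, and 327, 295 and 447 without LMC radial replicates 1, 2 and 3. The LMC radial count lower was 825 without phrenic replicate 4, 246 and 224 without C3-C5 GFP-only replicates 2 and 3, and 259, 280 and 289 without LMC radial replicates 1, 2 and 3. For C3-C5 GFP-only cells the count higher was 51 and 49 without their replicates 2 and 3, and 60, 63 and 69 without LMC radial replicates 1, 2 and 3, and the count lower ranged from 2 to 27 over the arrays left out.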

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

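The tests of correlation within the mesenchyme list and of 3′ bias, and both tests of phrenic replicate 4, were chosen after the result was seen. The splits of the arrays and the tests of quantile normalization and of shared probes were written beforehand.

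Mesenchyme and cartilage markers were higher in phrenic than in C3-C5 GFP-only arrays by a median of 1.37 on the log2 scale. A candidate source is cells of other types in the sorted samples, in amounts that vary between arrays, although the sort took cells by the reporter and the dextran and would remove unlabelled mesenchyme. After removal of type means the members correlated across arrays with a mean r of 0.355, at percentile 100 of random lists (median 0.00417), as such cells would give. Of the 18 members 1 is in another list and 10 lie above the median of all probe sets in C3-C5 GFP-only arrays, and Col1a1 lay at 8.22, 7.17, 9.63 and 9.28 in phrenic replicates 1 to 4 against 5.40 to 6.86 in C3-C5 GFP-only, and Col3a1 at 6.67 to 9.27 against 5.89 to 6.32. A difference in 3′ bias is argued against, since 85.5% of the median difference was left with the covariate, while expression of these genes by phrenic neurons themselves stays open and was not tested.

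Higher calls in LMC radial against C3-C5 GFP-only lay mostly in dim probe sets. Different value distributions of the arrays may contribute, as 72.5% of the 673 dim higher calls were left after quantile normalization. Shared probes stay open too, since the share of probe sets whose names mark probes shared with other genes was 1.68 times that among all dim probe sets (11.7% against 7.0%). With the Gapdh and Actb covariates for 3′ bias 41.01% and 22.3% of the dim higher calls were left, but 59.3% and 40.0% of the bright lower calls were, so the loss was not particular to dim probe sets. The median difference of the dim ones moved from 0.77 (median SE 0.15) to 0.71 (0.16) and 0.69 (0.17). Most of it was thus left with either covariate. The Actb difference spanned only 1.01 to 1.12 in LMC radial arrays, so the covariate slope rests mainly on the other types. These fits therefore cannot decide whether 3′ bias is a source of the dim differences. Array distributions, shared probes and 3′ bias cannot be told apart from a difference between the cell types.

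Phrenic replicate 4 stood apart from the other phrenic arrays, with a mean correlation of 0.967 to them. Cells of the C3-C5 GFP-only type could give this, and over genes higher and lower in phrenic neurons its median position lay 45.8% and 24.9% of the way to C3-C5 GFP-only, with 20% and 20.6% for phrenic replicate 2. Of 10 lists of other cell types 7 had their highest phrenic mean in replicate 4. Neither test decided between these sources for a single array, and a biological difference of that sample was not tested.

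Chance gives an array far from its replicates in about 1 in 20 groups, and 27 of 338 groups of values had one. The lists were motor neuron identity in phrenic replicate 4 (8.74), sodium and calcium channels (7.72) and hypoxia and glycolysis (8.83) there too, Eph and ephrin genes in phrenic replicate 2 (6.61), and cholesterol synthesis in phrenic replicate 3 (9.53). In C3-C5 GFP-only cells they were immunoglobulin adhesion genes in replicate 4 (8.27), and Wnt genes (5.79), neurofilament and axon genes (11.8) and cell cycle genes (5.48) in replicate 1. Among genes, phrenic replicate 4 stood apart for Cdh10 (10.31), Cdh9 (7.05), Hs3st4 (9.69), Klf5 (6.71), Npy (7.20) and Crabp1 (10.91), phrenic replicate 3 for Crnde (7.99) and phrenic replicate 2 for Tspan8 (5.14). C3-C5 GFP-only replicate 1 stood apart for Adam12 (6.37), Gfra1 (9.79), Klf5 (4.77), Pou3f1 (10.43) and Synpr (6.39), replicate 2 for Cbln4 (7.32), and replicate 4 for Foxp1 (12.48), Lss (10.01), Cntnap4 (5.15) and Neurod2 (6.88). The 3 LMC radial arrays are too few for this test.

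Other splits of the arrays into groups of equal sizes were refitted, and each number of splits out of 100 or 35 includes the real split. For phrenic against the mean of the others 2 of 100 splits, the real one and 1 drawn at random, gave as many called probe sets as the real 1733. Few splits reached that count, but 1 drawn split exceeded it, so chance is not excluded. The highest other value was 1974, from the split that puts phrenic and C3-C5 GFP-only replicates 2 and 3 together, the 4 arrays with the lower 25th percentile, and the real comparison gave 1890 with the array set as a block and 511 within the higher set. No drawn split reached the real count, so that the real split is the 1, for LMC radial (1 of 100, 3163 against at most 2367) and C3-C5 GFP-only (1 of 100, 438 against 238), each against the mean of the others. The same held, again with the real split as the 1, for probe sets set apart in phrenic (1 of 100, 530 against 248), LMC radial (1 of 100, 1148 against 717) and C3-C5 GFP-only (1 of 100, 118 against 0). The 2367, 238 and 717 came from a drawn split that kept the 3 LMC radial arrays together. The 248 came from 1 that kept the 4 phrenic arrays together. These maxima can therefore hold real differences between types.

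The draw missed 1 split that follows the array set, with replicates 1 and 4 of phrenic and C3-C5 GFP-only in 1 group, their replicates 2 and 3 in the other, and LMC radial kept. It gave 3718 for LMC radial and 5354 for C3-C5 GFP-only against the mean of the others, and set 232 apart in C3-C5 GFP-only, where the real values were 3163, 438 and 118. Since LMC radial was kept, the 3718 contrasts the same arrays as the real 3163, with another residual spread. That count is thus no test of the LMC radial result. For C3-C5 GFP-only the values point to a structure of the arrays that the types do not explain. The draw alone does not separate these results from the array set. With the array set as a block the real comparisons gave 1550 for LMC radial and 386 for C3-C5 GFP-only, and set apart 89 higher and 4 lower in C3-C5 GFP-only. Within the higher set they gave 551 and 24, and 13 higher and 2 lower. Of 102 splits, the real one not among them, that exchange arrays between 2 types and keep the third, 1, 1 and 3 gave as many called probe sets as the real phrenic, LMC radial and C3-C5 GFP-only comparisons with the mean of the others, and 0, 0 and 1 as many set apart. The 1 for LMC radial is the split that follows the array set. The 1 for phrenic (1962) put phrenic replicate 4 with the 3 LMC radial arrays, against the other phrenic arrays, and so kept most of each type together.

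For single pairs of types no other split reached the real count, with the real split as the 1, for phrenic against C3-C5 GFP-only (1 of 35, 882 against 266), phrenic against LMC radial (1 of 35, 2979 against 1535) and LMC radial against C3-C5 GFP-only (1 of 35, 1694 against 6). A share of 1 of 35 is the smallest that these splits can give. The 266 came from the split that follows the array set. The 1535 came from the split that put phrenic replicate 4 with the 3 LMC radial arrays, against the other phrenic arrays. For the number of lists called by camera chance cannot be excluded. In the order of the 6 comparisons 27, 21 and 5 of 100 and 4, 8 and 5 of 35 splits, the real one included, called as many as the real 10, 10, 15, 12, 12 and 10, with up to 15, 15, 17, 16, 19 and 12 in other splits.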

How the results depend on the processing

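The fits by array set, without phrenic replicates 1 and 4 together, and with the Actb, Gapdh or mesenchyme covariate were chosen after seeing the data. Values below follow 1 order. For totals of called probe sets it is phrenic, LMC radial and C3-C5 GFP-only against the mean of the others, phrenic against C3-C5 GFP-only, phrenic against LMC radial, and LMC radial against C3-C5 GFP-only. For probe sets set apart from both other types it is higher and lower in phrenic, in LMC radial and in C3-C5 GFP-only. As reported these were 1733, 3163, 438, 882, 2979 and 1694, and 317, 213, 671, 477, 110 and 8. No probe set called as reported was called in the opposite direction under the alternatives below, gene means and fits of only 2 types aside, where this was not counted. Counts moved with most alternatives. Some alternatives bring a smaller number of arrays or of tests, or another estimate of the spread shared by the types. Apart from these the cause was not tested.

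With a floor, which raises values below 5 on the log2 scale to 5, the counts were 1035, 782, 200, 516, 1046 and 382, and 186, 141, 108, 163, 57 and 3. Without dim probe sets, those with a mean below the median of all, they were 1708, 1676, 461, 903, 1999 and 844, and 319, 214, 131, 434, 87 and 8. With the mean of all probe sets of a gene, so 18193 tests in place of 45037, they were 991, 1531, 299, 588, 1361 and 834, and 203, 122, 256, 237, 81 and 14. Array weights gave 1673, 6864, 1758, 1109, 3872 and 6685, and 414, 258, 1260, 1191, 225 and 55. Quantile normalization gave 1714, 2534, 411, 898, 2680 and 1353, and 299, 245, 632, 322, 90 and 17. Centring on the median gave 1679, 3678, 419, 894, 3227 and 1904, and 297, 243, 937, 390, 99 and 20. A variance prior with a trend and robust fitting gave 1827, 3451, 561, 1021, 3235 and 1907, and 359, 239, 837, 443, 115 and 20. Fits of only the 2 types compared gave 606, 1410 and 3676 for the last 3 totals.

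Among the added alternatives, fits within the 7 arrays with the higher 25th percentile gave 511, 551, 24, 127, 778 and 98, and 43, 56, 30, 38, 13 and 2, with fewer arrays. Within the 4 arrays with the lower one, phrenic against C3-C5 GFP-only gave 159, and the other comparisons had no value there. The array set as a block gave 1890, 1550, 386, 1194, 1996 and 840, and 351, 248, 336, 271, 89 and 4. Without phrenic replicates 1 and 4 together the counts were 2532, 6721, 627, 1045, 5574 and 3529, and 524, 284, 1052, 1198, 127 and 24. The Actb covariate gave 1179, 860, 391, 1031, 1026 and 550, and 250, 194, 147, 184, 71 and 2. The Gapdh covariate gave 1576, 1527, 455, 1115, 1719 and 875, and 321, 231, 280, 283, 87 and 6. The mean of the mesenchyme and cartilage list as a covariate gave 1048, 3234, 140, 325, 2703 and 778, and 133, 103, 213, 261, 69 and 6.

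Blocking on the replicate number, as if numbers paired the arrays, gave 1795, 4029, 498, 862, 3537 and 2401, and 356, 198, 841, 758, 139 and 11. Of 10 pairs of arrays with equal numbers 4 had a correlation above 0.1 after removal of type means (range -0.0835 to 0.224), and these were all 4 pairs of phrenic with C3-C5 GFP-only (0.125 to 0.224). The 4 pairs of these types with different numbers within an array set had correlations of 0.179 to 0.28, and the 8 across array sets of -0.254 to -0.125, so array set and number overlap here. Of 11 arrays 1 correlated best with an array of its own number, and the numbers were not used as pairs. With this block the calls of Ahnak, Cdk1, Pou3f1 and Slc1a3 in phrenic against C3-C5 GFP-only ended. Against the mean of the others, it ended Fn1, Foxc1, Gja1, Itga1, Mnx1, Nid1, Pou3f1 and Zfp36l1 in C3-C5 GFP-only, and Hoxc6, Isl1 and Mnx1 in phrenic. In LMC radial against C3-C5 GFP-only it ended Igf2.

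Leaving out 1 array at a time, the totals ranged over 1202 to 2368, 1573 to 4746, 119 to 654, 458 to 1240, 1678 to 4266 and 606 to 2654, and the set-apart counts over 180 to 529, 149 to 290, 268 to 882, 224 to 825, 49 to 156 and 2 to 27. The lists called by camera, 10, 10, 15, 12, 12 and 10 as reported, ranged over 9 to 13, 8 to 12, 12 to 15, 9 to 15, 10 to 14 and 9 to 14. They were 10, 12, 15, 12, 7 and 14 with the Actb covariate, 10, 12, 15, 13, 7 and 14 with the Gapdh covariate, 5, 8, 7, 6, 11 and 7 with the mesenchyme covariate, 0, 1, 2, 0, 0 and 2 with an estimated correlation, and 12, 15, 11, 11, 17 and 11 with fry.

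Some values turned direction. Hoxc4, not called as reported, was at -0.00498 against the mean of the others in LMC radial neurons with the array set as a block and within the higher array set, and at -0.0428 in phrenic neurons without their replicates 1 and 4. Lhx1, also not called, was at -0.17 in C3-C5 GFP-only cells within the higher array set. With the mesenchyme covariate 4 lists turned in C3-C5 GFP-only against the mean of the others, at adjusted p = 0.256 for progenitors, 0.432 for cell cycle, 0.115 for macrophages and microglia and 0.642 for oxidative phosphorylation. In phrenic against C3-C5 GFP-only, progenitors (0.241), cell cycle (0.903) and oxidative phosphorylation (0.987) turned. None of these 7 was past the test after turning. Of the values computed for named genes under alternatives 6270 kept direction and side of the threshold, 606 lost the call, 31 gained it and 4 turned. For called lists 1644 kept both, 250 lost the call and 7 turned. In data with simulated changes, 60% to 85% of 2-fold and 96% to 98% of 4-fold changes passed over the 6 comparisons. Recovery was not split by signal level, and the simulated noise was independent for each probe set. Each of the 6 totals was lower with the floor, which removes differences at low signal. The floor also ended calls of genes whose difference it left as reported. Examples are Isl1 in phrenic against the mean of the others (1.51, limma adjusted p = 0.141) and Ahnak in phrenic against C3-C5 GFP-only (2.34, 0.0969). The lower totals are thus not only a loss of differences at low signal.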

Other observations

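The gene lists below were fixed before the data were examined, and the test of a fixed share of phrenic cells at the end was chosen after its result was seen.

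Between phrenic neurons and the mean of the other types, members of guidance and ion channel lists changed in both directions. Of the slit, robo and netrin list 4 of 22 genes rose and 4 fell (5 and 7 adjusted over the list alone), with Flrt1 (2.42 ± 0.14) and Flrt2 (1.72 ± 0.22) higher and Slit1 (-1.23 ± 0.10) and Rgma (-1.99 ± 0.18) lower (log2 differences ± SE). Of the potassium channel genes 5 of 39 rose and 4 fell (11 and 5 adjusted over the list alone), Kcnc4 (2.03 ± 0.24) against Kcnip1 (-1.58 ± 0.14), Kcnab1 (-1.69 ± 0.15) and Kcnd2 (-1.78 ± 0.30). Camera called neither list as a whole (adjusted p = 0.63 and 0.216). The synaptic vesicle list had 3 of 25 genes higher and 0 lower (3 and 1 adjusted over the list alone), among them Sv2b (1.06 ± 0.17) and Syn2 (0.996 ± 0.18), and its call (adjusted p = 0.0407) was lost at adjusted p = 0.472 with an estimated correlation.

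In LMC radial neurons the retinoid list had 3 of 17 genes higher and 2 lower (3 and 5 adjusted over the list alone), with Stra6 (1.43 ± 0.20), a retinol transporter, higher and Crabp1 (-2.56 ± 0.29), a retinoic acid binding protein, lower. Camera did not call it (adjusted p = 0.963). The nicotinic receptor subunit Chrna3 (-2.69 ± 0.29) and the netrin receptor Unc5c (-1.48 ± 0.15) were lower, and the glycine receptor subunit Glra2 (1.03 ± 0.13) was higher.

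For 125 genes at least 4-fold higher in phrenic than in LMC radial neurons, the C3-C5 GFP-only value often lay between both. Genes lower in phrenic neurons were not used. A hypothesis is that C3-C5 GFP-only samples may hold a fixed share of unlabelled phrenic neurons, with the rest like LMC radial for these genes. Each gene then implies a share on the linear scale, and these shares should agree within the spread of replicates. The implied shares had a median of 32.9% and quartiles of 15.7% and 59.9%. Their interquartile range of 44.2 percentage points was 3.77 times the 11.7 simulated for 1 common share. One fixed share alone therefore did not account for these genes. A share that adds to other differences between the types was not excluded.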
